A study of Mus musculus with 4 samples.

How the data were processed

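The series holds 4C-seq libraries of CD4- CD8- thymocytes (DN, Rag2-/-) and naive B splenocytes (B, wild type) of C57BL/6 mice, with 2 samples per cell type and 4 viewpoints per sample, 16 libraries in all. Per the labels, chromatin was digested with HindIII, religated, digested with DpnII, religated and amplified by inverse PCR. The protocol text of the B samples repeats that of the thymocytes, and how the B cells were isolated is not given in the sources used here. The submitters' processing notes name CASAVA and Bowtie and the build mm9, without versions or settings.

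The deposited files give, for each HindIII fragment with reads, its reads scaled to the mapped reads of that library (RPM), a normalization done by the authors. Per the file headers the fragments were padded by 40 bp. The deposited RPM values of each library sum to between 989622 and 1002693. In every library 100% of the values were whole multiples of the value of 1 read, within 0.01 read, and the mapped total of a library was taken from that value. Reads were recovered on this basis for the libraries of the INT1, INT2 and Ed viewpoints, and tests on counts were run for those viewpoints only, because the value of 1 read in DN replicate 2 of TEA is too close to a rounding step to tell counting from rounding. The authors also deposited 8 files of mean RPM, of which 7 equal the mean of their own replicates within 0.001 RPM. The mean deposited for INT2 in B cells holds the DN values, and no mean was used. Per the file headers the libraries come from 3 sequencing folders, 1 for each DN sample and 1 for both B samples, so 0 folders hold both cell types.

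A viewpoint fragment was the chromosome 14 fragment with the highest mean value. Library size was the chromosome 14 total outside the viewpoint fragment and 1 fragment on each side. Values were summed over 10 kb windows within 1 Mb of the viewpoint (without 10 kb around it, kept at a mean of at least 10 reads), over anchors (fragments within 10 kb of another viewpoint) and over the upstream (500 kb), inner and downstream (100 kb) segments. For each viewpoint limma 3.58.1 in R 4.3.3 was fitted to log2 of these sums, as RPM of the library size, with a pseudocount of 1 and a mean-variance trend, comparing 2 DN with 2 B libraries, two-sided. Fold changes are on this log2 scale with its pseudocount, which understates the change of low values. Adjusted p is Benjamini-Hochberg over the 8 anchor contacts, over the 12 segment contacts, or over the windows of a viewpoint, with a threshold of 0.05. Contacts on other chromosomes were numbers of captured fragments per 1 Mb window, fitted in limma with an offset of 0.5. Shares of reads were compared with exact permutation tests, for which the smallest p is 0.333.

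These tests, the alternatives other than those listed here as added, and the rule for named windows were fixed before the data were examined, with limma as the stated test for normalized values. The rule names every anchor and segment contact and, per viewpoint and direction, the 10 windows with the smallest adjusted p under 0.05 in which both DN libraries lie on the same side of both B libraries, or all that pass where fewer do. This gave 29 windows. No annotation of the build was at hand, so no gene was assigned to a window. Added after the data were seen were edgeR on recovered reads, limma without the trend, library size as chromosome 14 reads in excess of the density on other chromosomes, shares without 10 kb around the viewpoint or with that background subtracted, and similarity in 20 kb windows.

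The alternatives tried were TMM factors, library size over all chromosomes or within 1 Mb only, fragments capped at the 95th percentile, each captured fragment counted once, no filter, a replicate block, DESeq2 1.42.0 and edgeR 4.0.16, other window, anchor and segment sizes, a larger pseudocount (0.1 of the median value above 0, 50.7 to 90.9 by viewpoint), and each sample left out in turn. Where fragments were counted once, library size was the number of chromosome 14 fragments captured outside the viewpoint and its neighbours. In edgeR the chromosome 14 library size was used, while DESeq2 used size factors over the tested windows, which centre those windows. The window test was tested on simulated data in 20 simulations, with 1 spread per viewpoint taken from the median squared difference between replicates. All windows of a viewpoint had that spread, which lies below the SD for normal values. Recovery may therefore be overstated and false calls understated. In these simulations the window test recovered 38.2%, 82.5%, 44.5% and 8.50% of 4-fold changes from TEA, INT1, INT2 and Ed, with at most 1.2 false calls on average. In the test of other chromosomes, 1 simulation with a set spread of 0.2 on the log2 scale recovered 91% to 100% of 4-fold and 19% to 50% of 2-fold changes, with 4, 5, 1 and 6 false calls from TEA, INT1, INT2 and Ed. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.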

Results

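Chromatin contacts of the mouse T cell receptor alpha and delta locus (Tcra/Tcrd) were measured by 4C-seq in double-negative (CD4- CD8-) thymocytes, here DN, and in naive B cells of the spleen, here B. In 4C-seq, crosslinked DNA is digested and religated, and inverse PCR from a chosen fragment, the viewpoint, recovers the fragments ligated to it. DN cells came from Rag2-/- mice, which cannot assemble antigen receptor genes, and B cells from wild-type mice, so genotype and tissue differ together with cell type. Each cell type had 2 samples, and each sample was read from 4 viewpoints, which makes 16 libraries. TEA (T early alpha) is a germline promoter element at the 5′ end of the Jα array, and Ed (E-delta) is the Tcrd enhancer between the Jδ segments and Trdc. The labels give no definition of INT1 and INT2.

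The viewpoint fragments lay on chromosome 14 (build mm9) at 54677060 to 54677623 for INT1, 54680988 to 54683873 for INT2, 54763263 to 54765182 for Ed and 54769627 to 54773311 for TEA. INT1 and INT2 were 5.09 kb apart and were joined into 1 INT anchor as a target. Ed and TEA were 7.25 kb apart, so the regions of 10 kb around them overlap. TEA was 89.0 kb from INT2 and 94.1 kb from INT1. The only gene annotation at hand was of another build, so windows carry positions and no genes. In that annotation 130 Trav genes lie on the lower-coordinate side of Trdd1, followed by Trdd2, the Trdj genes and Trdc, with 60 Traj genes beyond Trdc.

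The libraries held between 1.22 and 17.3 M mapped reads, as worked out from the value of 1 read in each file, and 169129 to 2851909 of them fell on chromosome 14 outside the viewpoint. From TEA the DN libraries had 2037531 and 9988342 reads and the B libraries 11434923 and 17287420. The depth of DN replicate 2 from TEA is less certain than the others, because the value of 1 read there is close to a rounding step. From INT1 they had 15046827 and 4846919 in DN and 7191700 and 9546301 in B. INT2 gave 1907814 and 7457367 reads in DN and 11814951 and 15722920 in B. Ed gave 1220738 and 3227300 reads in DN and 3531308 and 6283713 in B. PCR reads without molecular identifiers are not independent molecules, so floors given below cover counting error only. The labels describe the DN material as taken from litters and do not say whether replicates came from separate litters, so the p-values measure the spread between samples.

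How strongly reads stayed near the viewpoint was compared first, because every contact value depends on it. Reads from all 4 viewpoints were more concentrated near the locus in DN thymocytes than in B cells. The share of chromosome 14 reads lying within 1 Mb of the viewpoint was 70.1% ± 9.92 in DN and 22.4% ± 0.966 in B from TEA (SD, n = 2). From INT1 it was 69.7% ± 9.30 against 39.9% ± 0.545, from INT2 69.3% ± 7.56 against 26.1% ± 0.560, and from Ed 63.7% ± 0.343 against 38.8% ± 2.88. Chromosome 14 outside the viewpoint took 22.2% ± 9.88 of reads in DN and 7.05% ± 0.0849 in B from TEA, and 22.6% ± 10.2 against 8.97% ± 0.0629 from INT1. It took 19.97% ± 5.45 in DN against 7.65% ± 0.307 in B from INT2, and 18.5% ± 4.51 against 8.84% ± 0.382 from Ed. With each sample left out in turn, the difference in this chromosome 14 share ranged from 8.20 to 22.2 points from TEA and 6.40 to 20.9 from INT1. It ranged from 8.46 to 16.2 from INT2 and 6.50 to 12.9 from Ed. Each DN library exceeded each B library in both shares. A two-sided exact permutation test gave p = 0.333 for each difference, which is the smallest p that 2 samples against 2 can give, so the comparison cannot pass 0.05. After subtraction of the background expected from reads on other chromosomes, the differences in the share within 1 Mb were 27.4 points from TEA, 8.46 from INT1, 25.3 from INT2 and 5.73 from Ed. From Ed the cell types then overlapped, with a lower DN share of 76.9% and a higher B share of 82.8%. The sequencing folder also separates the cell types completely.

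**Figure D1:**
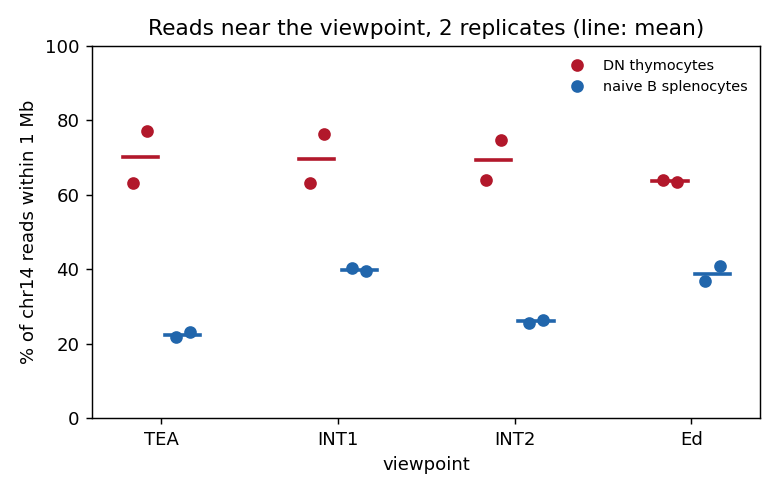
Share of chromosome 14 reads within 1 Mb of the viewpoint (vertical axis, percent) in each library, by viewpoint and cell type, with points for libraries and short lines for the mean of 2 replicates. The DN mean is highest from TEA, at 70.1%, and the B means range from 22.4% to 39.9%.

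The title of the series asks about a chromatin loop in this locus, and the contacts of INT with TEA and Ed address it directly. All 8 contacts between the INT, Ed and TEA regions made up a larger share of chromosome 14 reads in DN thymocytes than in B cells. TEA contacted the INT anchor with 11.5% ± 3.66 of chromosome 14 reads in DN and 2.49% ± 0.0840 in B (SD, n = 2), a fitted rise of 4.49-fold. In the opposite direction, INT2 contacted the TEA anchor with 10.3% ± 3.74 in DN and 1.59% ± 0.390 in B, 6.36-fold higher. INT2 contacted the Ed anchor with 8.70% ± 1.67 in DN and 1.49% ± 0.665 in B, 6.08-fold higher. The Ed anchor includes the TEA fragment, which alone took 4.50% ± 2.02 in DN and 0.788% ± 0.144 in B from INT2. Contacts of INT with Ed and with TEA therefore share reads and are not separate contacts. These folds depend on the denominator. Reads at the density of other chromosomes would make up 63.9% of chromosome 14 reads in B and 19.6% in DN from TEA. With the excess over that density as library size, the log2 change was 1.02 for TEA with INT, 1.71 for INT2 with TEA and 1.65 for INT2 with Ed.

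INT1, beside INT2, contacted TEA with 3.06% ± 1.65 in DN against 0.699% ± 0.0151 in B, 4.04-fold higher, and Ed with 2.56% ± 1.16 against 0.794% ± 0.105, 3.06-fold higher. The Ed viewpoint contacted INT with 0.747% ± 0.272 in DN and 0.155% ± 0.0191 in B, 4.65-fold higher. TEA contacted the Ed anchor with 19.3% ± 5.09 in DN and 7.13% ± 0.137 in B, 2.66-fold higher, and Ed contacted the TEA anchor with 5.30% ± 1.61 against 2.28% ± 0.312, 2.28-fold higher. Anchors kept fragments within 10 kb of the viewpoint, which windows and segments left out, so contacts between TEA and Ed include ligation close to the viewpoint. The second-highest fragment from TEA, at 54768785 to 54769466 (mean 15596 RPM), lies in the Ed anchor. Both DN libraries lay above both B libraries in each of the 8 contacts.

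In limma the adjusted p was 0.00377 for TEA with INT (log2 change 2.17, SE 0.35), for INT2 with TEA (2.67, SE 0.40) and for INT2 with Ed (2.61, SE 0.43). It was 0.00407 for TEA with Ed (log2 change 1.41, SE 0.29), 0.00528 for INT1 with TEA (2.02, SE 0.49) and 0.0110 for INT1 with Ed (1.61, SE 0.46). For Ed with INT the adjusted p was 0.0235 (2.22, SE 0.62) and for Ed with TEA 0.0351 (1.19, SE 0.39). With library size taken within 1 Mb only, 0 of the 8 contacts passed in limma and TEA with Ed turned to -0.22. With TMM factors only 1 of 8 passed, TEA with INT (limma adjusted p 0.0305), and with each captured fragment counted once 3 of 8 passed. Of these 3, INT2 with Ed stood at 0.79, the value that equal numbers of captured fragments in all 4 libraries give. That value comes from the library size, since the B libraries captured more chromosome 14 fragments from INT2. Ed with TEA turned to -0.0044 with TMM factors, -0.14 in DESeq2 and -0.23 with 20 kb anchors. Without the mean-variance trend 0 of 8 passed, at limma adjusted p from 0.0995 to 0.337. With each sample left out in turn, every log2 change stayed above 0. The changes were 0.88 to 2.60 without DN replicate 1 and 1.13 to 3.05 without DN replicate 2. They were 1.05 to 3.08 without B replicate 1 and 1.33 to 2.41 without B replicate 2. Not every contact kept its call in every omission, and each such fit leaves 1 sample in a group.

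**Figure D2:**
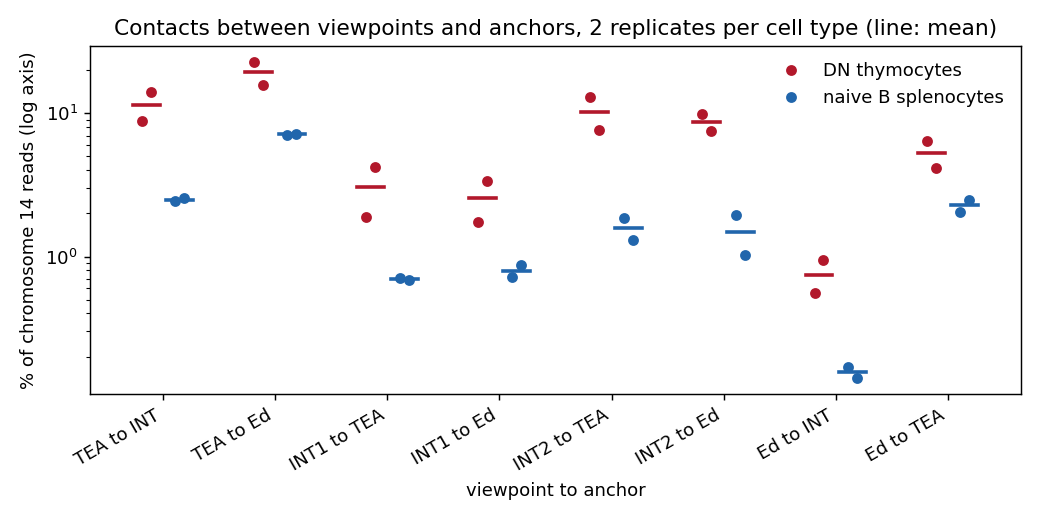
Share of chromosome 14 reads (vertical axis, percent, log scale) that each viewpoint placed on each other anchor, with points for libraries and short lines for the means of DN and B. Both DN points lie above both B points in each of the 8 contacts, from 0.747% against 0.155% for Ed with INT up to 19.3% against 7.13% for TEA with Ed.

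Most tested windows near the viewpoints had a higher share in DN thymocytes, so each contact was also set against the median 10 kb window within 1 Mb. The fitted log2 change was above 0 in 157 of 193 windows from TEA, 151 of 195 from INT1, 133 of 192 from INT2 and 91 of 140 from Ed, with medians of 1.49, 1.53, 1.21 and 1.71. Relative to that median, INT2 stood at 1.46 on the log2 scale with TEA and at 1.40 with Ed. TEA stood at 0.67 with INT, Ed at 0.51 with INT and INT1 at 0.49 with TEA. INT1 with Ed stood at 0.09, TEA with Ed at -0.08 and Ed with TEA at -0.52. These relative values were not tested, and they changed with the processing. With fragments capped at the 95th percentile, INT2 with TEA stood at 0.89, INT2 with Ed at 0.95, INT1 with TEA at 0.56, INT1 with Ed at 0.30, Ed with INT at 0.71, TEA with INT at 0.0043, TEA with Ed at -0.38 and Ed with TEA at -1.15. With each captured fragment counted once, 7 of the 8 contacts lay below the median window, INT2 with TEA at -0.18, INT2 with Ed at -0.24, TEA with INT at -0.12 and INT1 with TEA at -0.18 among them, and Ed with INT stood at 0.52. That count saturates close to the viewpoint, since INT1 and INT2 each captured 29 of 29 inner fragments in both DN samples. Without the filter Ed with INT stood at 0.82 and Ed with TEA at -0.20, and in DESeq2 at 0.92 and -0.03. With the larger pseudocount Ed with INT stood at 1.41, Ed with TEA at 0.42 and TEA with Ed at 0.24. Over 6 choices of library size Ed with INT ranged from 0.50 to 1.06, Ed with TEA from -0.52 to 0.04 and TEA with Ed from -0.10 to 0.12. These choices moved the median window itself from -0.12 to 2.87 for TEA, from 0.41 to 2.60 for INT1, from -0.07 to 2.39 for INT2 and from 0.52 to 2.20 for Ed.

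Contacts were then summed over 3 segments, to ask which side of each viewpoint changed. The segments were the 500 kb on the lower-coordinate side of INT (upstream), the stretch from INT to TEA (inner) and the 100 kb beyond TEA (downstream). Segments include anchor fragments, so they share reads with the anchor contacts. In DN the inner segment holds 7.17% of chromosome 14 reads on the fragment beside INT2 from TEA, and 4.50% on the TEA fragment from INT2. In DN thymocytes INT2 placed 26.7% ± 0.316 of chromosome 14 reads on the inner segment and in B cells 4.59% ± 0.465 (SD, n = 2). TEA placed 24.7% ± 5.75 on the inner segment in DN and 5.80% ± 0.548 in B. INT1 rose most on the upstream segment, with 21.0% ± 4.21 in DN and 3.25% ± 0.615 in B, and rose less on the inner segment, with 9.22% ± 3.41 against 3.11% ± 0.382.

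The inner segment had log2 changes of 2.55 from INT2 (SE 0.29) and 2.07 from TEA (SE 0.29), each at a limma adjusted p of 0.00154, and 1.52 from INT1 (SE 0.55, adjusted p 0.0293) and 1.74 from Ed (SE 0.50, adjusted p 0.0293). The upstream segment had 2.69 from INT1 (SE 0.59, adjusted p 0.00379), 2.23 from INT2 (SE 0.33, adjusted p 0.00274), 1.98 from TEA (SE 0.35, adjusted p 0.00274) and 1.91 from Ed (SE 0.59, adjusted p 0.0305). The downstream segment had 1.91 from INT1 (SE 0.50, adjusted p 0.00885), 1.86 from INT2 (SE 0.31, adjusted p 0.00369) and 1.40 from TEA (SE 0.36, adjusted p 0.00888). Ed with the downstream segment missed the threshold in limma (0.39, SE 0.34, adjusted p 0.308), with 3.32% ± 0.0121 in DN and 2.54% ± 0.238 in B. It passed with library size over all chromosomes (1.43, adjusted p 0.0421), capped fragments (1.09, adjusted p 0.00038) and each fragment counted once (1.04, adjusted p 0.0211), and turned to -0.81 with TMM factors, -1.01 in DESeq2 and -0.24 with the excess over other chromosomes. Both DN libraries lay above both B libraries for the 11 segments that passed.

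In the other segments the shares were 13.3% ± 4.01 in DN and 3.33% ± 0.642 in B for TEA upstream, and 4.50% ± 0.749 against 1.69% ± 0.106 for TEA downstream. INT2 had 14.5% ± 3.44 against 3.06% ± 0.377 upstream and 9.23% ± 1.65 against 2.52% ± 0.172 downstream. INT1 had 7.41% ± 2.37 against 1.93% ± 0.138 downstream. Ed had 7.83% ± 3.99 against 2.06% ± 0.970 upstream and 22.8% ± 12.5 against 6.40% ± 1.68 on the inner segment. With library size taken within 1 Mb only, 0 of 12 segments passed in limma, TEA downstream turned to -0.23 and Ed downstream to -0.33, and without the mean-variance trend 0 of 12 passed. Without DN replicate 2, B replicate 1 or B replicate 2, 0 of 12 segments passed (lowest adjusted p 0.0651, 0.0855 and 0.0907), and without DN replicate 1 3 of 12 did, with every log2 change still above 0 (0.29 to 2.90). Ed with the inner segment was 2.33 without DN replicate 1 and 1.15 without DN replicate 2.

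Windows of 10 kb within 1 Mb of the viewpoint were tested to locate the changes without choosing a target. From TEA, 5 windows rose in DN thymocytes and 0 fell, of 193 tested. All 5 lay between 54.57 and 54.75 Mb, on the INT side of TEA. The window at 54.73 to 54.74 Mb, between INT and Ed, held 3.31% ± 0.235 of chromosome 14 reads in DN and 0.368% ± 0.0711 in B (SD, n = 2), 9.05-fold higher. Its neighbour at 54.72 to 54.73 Mb was 8.26-fold higher, the window at 54.74 to 54.75 Mb 6.81-fold higher, and the window at 54.68 to 54.69 Mb, which holds INT2, 4.51-fold higher. The window at 54.57 to 54.58 Mb, beyond INT, held 0.915% ± 0.255 in DN and 0.0592% ± 0.0105 in B, 15.2-fold higher. The limma adjusted p was 0.0273 for 4 of these windows and 0.0295 for the window at 54.74 to 54.75 Mb, and 44 windows had an unadjusted p under 0.05. Without any 1 of the 4 samples (DN replicate 1 or 2, B replicate 1 or 2) 0 windows passed (25, 22, 41 and 49 at an unadjusted p under 0.05), and with TMM factors or library size within 1 Mb 0 passed, with 21 and 19 windows at an unadjusted p under 0.05. With each captured fragment counted once, 0 of these 5 windows kept their call. The windows from 54.68, 54.72 and 54.74 Mb then stood at a log2 change of 0.50. That is the value that equal numbers of captured fragments in all 4 libraries give, so for them this count cannot test a difference in reads.

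From INT2, 10 windows rose in DN thymocytes and 0 fell, of 192 tested, and they lay on both sides, 4 below and 6 above the viewpoint, between 54.46 and 54.85 Mb. The window at 54.73 to 54.74 Mb, also called from TEA, held 6.33% ± 0.885 in DN and 0.385% ± 0.0894 in B (SD, n = 2), 16.6-fold higher (log2 change 4.05, SE 0.35, limma adjusted p 0.0111). The window at 54.72 to 54.73 Mb was 10.3-fold higher (adjusted p 0.0227), the window at 54.76 to 54.77 Mb, which holds Ed, 7.69-fold higher (adjusted p 0.0248) and the window at 54.77 to 54.78 Mb, which holds part of TEA, 5.75-fold higher (adjusted p 0.0433). On the upstream side the windows at 54.49 to 54.50 and 54.46 to 54.47 Mb were 46.1-fold and 23.0-fold higher, from 0.0114% ± 0.00563 and 0.0331% ± 0.00197 in B. The other 4 windows were 4.41 to 14.7-fold higher. Of the 192 windows, 44 had an unadjusted p under 0.05. In limma 0 windows passed with TMM factors or with library size within 1 Mb (37 and 35 at an unadjusted p under 0.05). With chromosome 14 library size, edgeR called 7 higher and 0 lower. With size factors over the tested windows, DESeq2 called 16 higher and 10 lower. The median window stood at 1.07 in edgeR and 0.08 in DESeq2, so these splits differ in normalization as well as in test. Without DN replicate 1, DN replicate 2 or B replicate 1 0 passed (34, 29 and 50 at an unadjusted p under 0.05), and without B replicate 2, or without the mean-variance trend, 0 were higher and 6 or 3 lower.

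From INT1, 48 windows rose in DN thymocytes and 4 fell, of 195 tested, and 34 of the 48 lay on the lower-coordinate side. The 10 with the smallest adjusted p all lay between 54.39 and 54.62 Mb and were 7.27 to 26.9-fold higher. The window at 54.57 to 54.58 Mb, also called from TEA and from INT2, held 2.04% ± 0.304 in DN and 0.0841% ± 0.0534 in B (SD, n = 2), 26.9-fold higher (log2 change 4.75, SE 0.52, limma adjusted p 0.00129), with a log2 change of 4.06 without B replicate 1 and 5.45 without B replicate 2. The window at 54.50 to 54.51 Mb was 19.6-fold higher and the window at 54.61 to 54.62 Mb 11.1-fold higher, each at an adjusted p of 0.00129. Of the 4 windows that fell, the window at 55.46 to 55.47 Mb held 0.0290% ± 0.00552 in DN and 0.186% ± 0.0510 in B (log2 change -2.67, SE 0.74, adjusted p 0.0354). With each captured fragment counted once it stood at 0.29, the value that equal numbers of captured fragments give through the library size alone. The window at 55.58 to 55.59 Mb had 0 reads in both DN libraries and 964 and 455 in B, at least 535-fold lower in DN against a floor of 3 reads per library (adjusted p 0.0142), a bound of 279-fold without B replicate 1 and 790.5-fold without B replicate 2. The window at 55.49 to 55.50 Mb had 0 reads in DN and 173 and 42 in B, at least 83.8-fold lower (adjusted p 0.0484) or 25.7-fold without B replicate 1 and 142-fold without B replicate 2, and the window at 53.73 to 53.74 Mb had 1 and 0 reads in DN and 84 and 173 in B (adjusted p 0.0403). With each captured fragment counted once, the windows from 55.58 and 55.49 Mb both stood at only -1.30. Their bounds therefore rest on the reads of very few captured fragments and do not bound a difference in contacts. The split of higher and lower windows was 23 and 11 with library size within 1 Mb and 17 and 13 with TMM factors. It was 29 and 28 in DESeq2, with size factors over the tested windows, and 42 and 2 in edgeR, with chromosome 14 library size. Without DN replicate 1 or without DN replicate 2 10 windows passed, of which 1 was among the 14 named windows (54.61 to 54.62 Mb), and without B replicate 1 or 2 33 and 47 passed, with 12 and 13 of the 14. With each captured fragment counted once, 0 of the 14 kept their call.

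From Ed, 0 of 140 windows passed in limma, and 20 had an unadjusted p under 0.05. The edgeR test also called 0, and DESeq2, with size factors over the tested windows, called 14, of which 10 were lower. The median-based spread between replicates was 1.32 on the log2 scale from Ed and 0.51 from INT1. On data simulated with that 1 spread for all windows of a viewpoint, the test recovered 8.50% of 4-fold and 37.5% of 16-fold changes from Ed, against 82.5% and 99.8% from INT1. In the data the spread differed by window, with SEs from 0.38 to 2.17 among the named INT1 windows, so these rates may be too high. Without DN replicate 1, 16 windows passed and without DN replicate 2, 12, all higher in DN. Of the windows called higher, TEA and INT1 shared 4 of 182 tested in both, where 1.24 would be shared if calls were independent. TEA and INT2 shared 3 of 180 (0.18), and INT1 and INT2 9 of 190 (2.47). The viewpoints were read in the same 4 samples, so their calls are not independent.

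**Figure D3:**
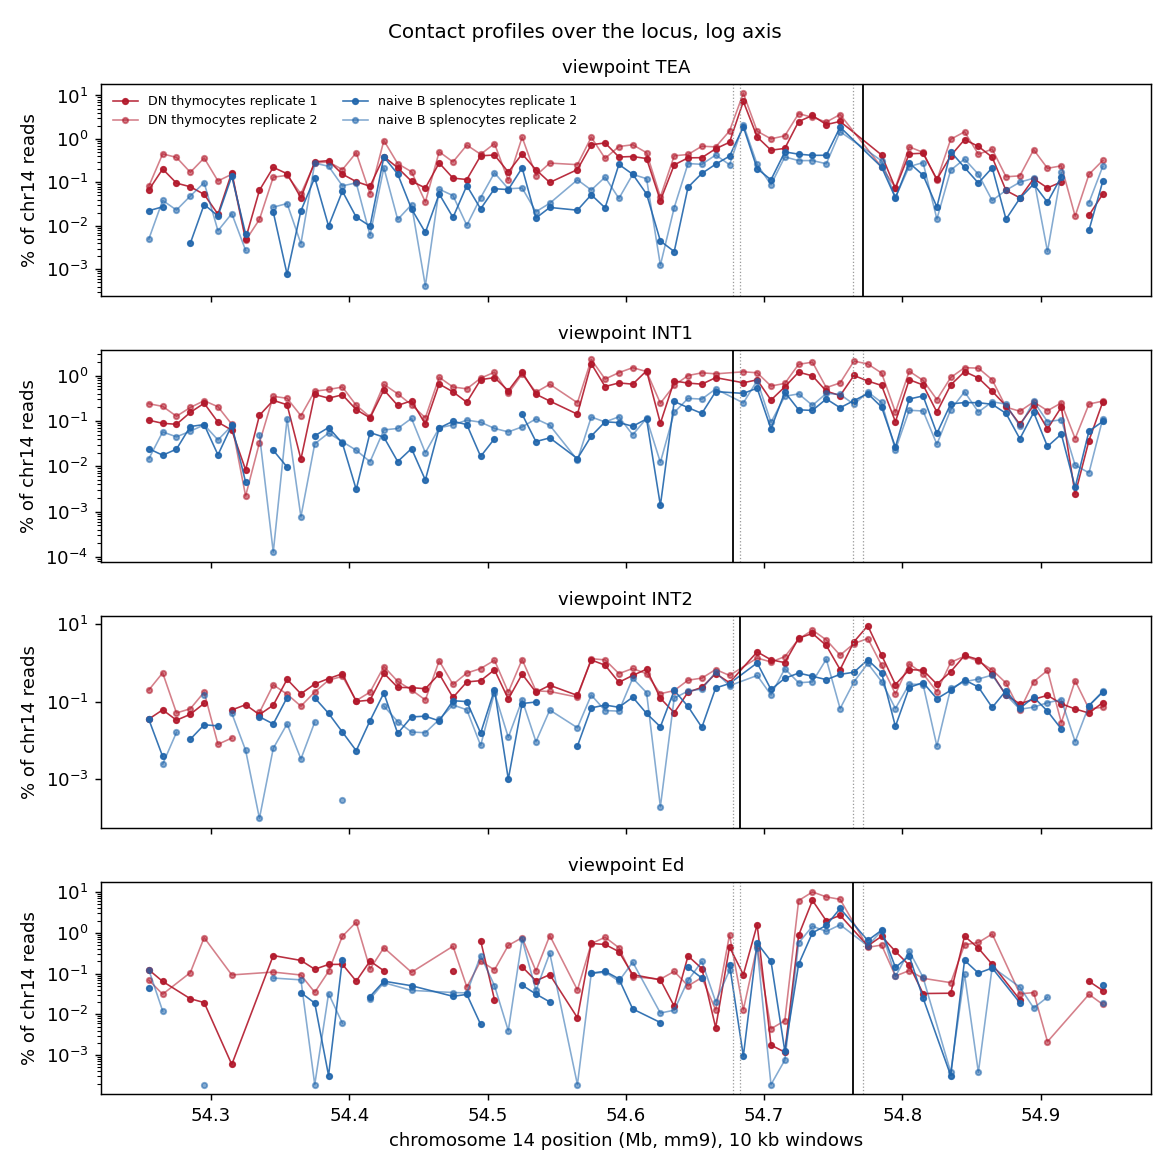
Share of chromosome 14 reads per tested 10 kb window (vertical axis, percent, log scale) against position on chromosome 14 (horizontal axis, Mb), a panel per viewpoint and a line per library, with the own viewpoint in black, the other viewpoints dotted and windows at 0 not drawn. From TEA and INT2 both DN lines lie above both B lines in the window from 54.73 Mb, where the DN means were 3.31% and 6.33% and the B means 0.368% and 0.385%.

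How alike replicates and neighbouring viewpoints were was described by correlation across 10 kb windows, which are not independent replicates. DN thymocyte replicates resembled each other most from INT1, with r = 0.849 over 195 windows, and B cell replicates gave 0.647. From TEA the DN pair gave r = 0.682 and the B pair 0.505, from INT2 0.693 and 0.381, and from Ed 0.572 and 0.386. Between cell types r was 0.444 to 0.536 from TEA, 0.413 to 0.488 from INT1, 0.377 to 0.408 from INT2 and 0.130 to 0.452 from Ed. Spearman's rho for the DN and B pairs was 0.825 and 0.587 from TEA, 0.922 and 0.799 from INT1, 0.794 and 0.640 from INT2, and 0.639 and 0.396 from Ed. INT1 and INT2, 5.09 kb apart, gave r = 0.682 and 0.736 with each other in the DN samples and 0.516 and 0.592 in the B samples, over 190 windows.

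Contacts with other chromosomes were compared as captured fragments per 1 Mb window. INT1 had 1 window with more fragments in DN thymocytes, on chromosome Y from 1 Mb, with 40 and 22 fragments in DN and 15 and 14 in B (log2 change 1.64, limma adjusted p 0.00794, higher in both DN libraries). INT2 had 2, on chromosome 5 from 23 Mb with 28 and 55 fragments in DN and 32 and 30 in B (1.48, adjusted p 0.00259), and on chromosome 19 from 46 Mb with 19 and 27 against 16 and 23 (1.37, adjusted p 0.0161). In these, 1 DN library did not exceed both B libraries in fragments before scaling. The window from INT1 lies on a sex chromosome, and the sex of the animals was not part of the comparison. Among the windows with the smallest p from INT1, those on chromosome X, from 120, 121 and 131 Mb, were lower in DN. Their log2 changes were -0.97, -0.87 and -0.83, and they did not pass in limma (adjusted p 0.0898 to 0.165). A difference in sex chromosomes therefore cannot be told apart from a contact there. From TEA 0 of 2457 windows and from Ed 0 of 1815 passed in limma, with 171 and 106 at an unadjusted p under 0.05. Without DN replicate 1 309 windows passed from TEA, 155 from INT1, 142 from INT2 and 31 from Ed, and without DN replicate 2 0, 2, 48 and 0. Without B replicate 1 only 1 passed, from INT2, and without B replicate 2 0 passed.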

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

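The test below was chosen after the data were seen. Beyond 1 Mb from the viewpoint, chromosome 14 was not part of the report's comparisons, and its 100 kb windows were tested in limma. From Ed, the window from 64800001 to 64900000 was lower in DN thymocytes, with a log2 change of -6.31 (SE 1.71, adjusted p 0.0293 over 97 windows). It held 0.0018% and 0.0177% of chromosome 14 reads in the DN samples and 0.905% and 0.232% in the B samples, from 3 and 1 captured fragments in DN and 2 and 7 in B. The median window beyond 1 Mb was itself lower in DN, by log2 changes of -1.31 from Ed, -1.996 from TEA, -1.43 from INT1 and -1.71 from INT2. From TEA, INT1 and INT2 limma called 0 of 1026, 912 and 472 windows, with 142, 122 and 63 at an unadjusted p under 0.05.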

How the results depend on the processing

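The alternatives chosen after seeing the data were edgeR, limma without the trend, the excess over other chromosomes as library size, the other definitions of the shares, and similarity in 20 kb windows; the rest were fixed before. Unless stated, the cause of a value below changing side or sign was not tested. All 8 anchor contacts stayed higher in DN under library size over all chromosomes, 10 kb left out, capped fragments, each captured fragment counted once, no filter, replicate block, edgeR (6 contacts), no trend, excess over other chromosomes, 5 kb anchors and the larger pseudocount; the exceptions are named below. All 8 passed with all chromosomes, capped fragments, no filter, replicate block and 5 kb anchors. Of the 12 segments, 11 or 12 passed with all chromosomes, 10 kb left out, capped fragments, no filter and replicate block, and all 4 upstream segments of 1 Mb passed. The 29 named windows kept their direction in all settings except 1, the INT1 window at 55.46 to 55.47 Mb. It stood at 0.29 with fragments counted once, the value that equal numbers of captured fragments give through the library size alone. Their calls held less well, with 10 of 29 kept when fragments were counted once (the 10 from INT2), 14 with TMM factors, within 1 Mb or with the excess over other chromosomes, 9 without the trend, 1 without either DN replicate, 12 without B replicate 1 and 13 without B replicate 2. Counted once, library size was the number of captured chromosome 14 fragments, from INT2 4166 and 5108 in B and 2615 and 2731 in DN. Windows with equal captures in all 4 libraries then stand above 0, as at 0.79 for the INT2 windows from 54.76 and 54.70 Mb. The 10 calls kept from INT2 therefore need not mean more captured fragments in DN. DESeq2 and edgeR were not run for TEA, whose reads were not recovered in 1 library, and a random block for sequencing folder could not be estimated. Precision was lowest from Ed, where the median-based replicate spread was 1.32 on the log2 scale. With that spread in every window, simulated 4-fold changes were recovered in 8.50% of windows. What depth adds to that spread was not tested.

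The values below are log2 changes, DN minus B. With TMM factors the anchors no longer passing were 0.13 (TEA to Ed), 0.82 (INT1 to TEA), 0.42 (INT1 to Ed), 1.68 (INT2 to TEA), 1.61 (INT2 to Ed) and 1.02 (Ed to INT), and Ed to TEA turned to -0.0044 (adjusted p 0.0647 to 0.993). Segments no longer passing were 0.12 (TEA downstream), 0.33 (INT1 inner), 0.87 (INT2 downstream), 0.72 (Ed upstream) and 0.54 (Ed inner), and Ed downstream turned to -0.81. Called windows numbered 0 from TEA, 30 from INT1 (17 higher, 13 lower) and 0 from INT2.

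With library size within 1 Mb the anchors were 0.53 (TEA to INT), 1.22 (INT1 to TEA), 0.82 (INT1 to Ed), 1.26 (INT2 to TEA), 1.20 (INT2 to Ed), 1.50 (Ed to INT) and 0.47 (Ed to TEA), and TEA to Ed turned to -0.22 (adjusted p 0.114 to 0.489). The segments were 0.35 (TEA upstream), 0.44 (TEA inner), 1.89 (INT1 upstream), 0.72 (INT1 inner), 1.11 (INT1 downstream), 0.82 (INT2 upstream), 1.14 (INT2 inner), 0.46 (INT2 downstream), 1.20 (Ed upstream) and 1.02 (Ed inner), while TEA downstream turned to -0.23 and Ed downstream to -0.33. Called windows numbered 0 from TEA, 34 from INT1 (23 higher, 11 lower) and 0 from INT2.

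With the excess over other chromosomes as library size, 0.27 (TEA to Ed), 0.94 (INT1 to Ed), 1.59 (Ed to INT) and 0.56 (Ed to TEA) no longer passed (adjusted p 0.0579 to 0.409), nor did the segments at 0.25 (TEA downstream), 0.85 (INT1 inner), 0.91 (INT2 downstream), 1.28 (Ed upstream) and 1.11 (Ed inner), and Ed downstream turned to -0.24. TEA and INT2 had 0 called windows. Library size over all chromosomes brought Ed downstream past the threshold at 1.43 and gave 61, 87, 31 and 1 windows from TEA, INT1, INT2 and Ed. With 10 kb left out, Ed to TEA at 1.22 no longer passed (adjusted p 0.0627) and TEA had 8 windows.

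Capped fragments brought Ed downstream past the threshold at 1.09 and gave 10 windows from TEA, 19 from INT2 and 1 from Ed. With each captured fragment counted once, the anchors at 0.57 (TEA to INT), 0.50 (TEA to Ed), 0.35 (INT1 to TEA), 0.29 (INT1 to Ed) and 0.68 (Ed to TEA) and the segments at 0.53 (TEA inner), 0.91 (INT1 upstream), 0.46 (INT1 inner) and 0.48 (INT1 downstream) no longer passed, Ed downstream passed at 1.04, and windows numbered 43, 14, 80 and 26. TEA to Ed, INT1 to Ed and INT2 to Ed (0.79) stood where equal numbers of captured fragments in all libraries would put them.

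In DESeq2, 0.34 (INT1 to Ed), 0.81 (Ed to INT), 0.24 (INT1 inner), 0.43 (Ed upstream) and 0.36 (Ed inner) no longer passed, Ed to TEA turned to -0.14 and Ed downstream to -1.01, with 26 windows from INT2 (16 higher, 10 lower) and 14 from Ed (4 higher, 10 lower). Its size factors over the tested windows put the median window at 0.07 from INT1, 0.08 from INT2 and -0.11 from Ed. In edgeR, Ed to TEA at 1.22 no longer passed (adjusted p 0.0645). In limma without the trend the estimates stayed as in the report, at 2.17 (TEA to INT), 1.41 (TEA to Ed), 2.02 (INT1 to TEA), 1.61 (INT1 to Ed), 2.67 (INT2 to TEA), 2.61 (INT2 to Ed), 2.22 (Ed to INT) and 1.19 (Ed to TEA), and none passed (adjusted p 0.0995 to 0.337). The same held for the segments, upstream 1.98 (TEA), 2.69 (INT1), 2.23 (INT2) and 1.91 (Ed), inner 2.07, 1.52, 2.55 and 1.74, and downstream 1.40 (TEA), 1.91 (INT1) and 1.86 (INT2), with 0 windows from TEA, 17 from INT1 (14 higher, 3 lower) and 3 from INT2, where 0 were higher and 3 lower.

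With 20 kb anchors Ed to INT at 1.26 no longer passed and Ed to TEA turned to -0.23. With the larger pseudocount (50.7 to 90.9 by viewpoint, in place of 1) Ed to TEA at 1.19 no longer passed (adjusted p 0.0517) and windows numbered 14, 85 and 33 from TEA, INT1 and INT2. With an upstream segment of 200 kb, Ed upstream at 1.68 no longer passed (adjusted p 0.0790). Windows of 20 kb gave 3 from TEA, and single fragments 0 from TEA, INT1 and INT2 (121, 175 and 121 at an unadjusted p under 0.05 in limma). The difference in the share within 1 Mb was 27.4, 8.46, 25.3 and 5.73 points from TEA, INT1, INT2 and Ed after background subtraction, and 39.6 from INT1 and 31.3 from Ed with 10 kb left out. In 20 kb windows r of the DN pair was 0.837 from TEA, 0.890 from INT1 and 0.770 from INT2. On other chromosomes, reads gave 1 window from TEA and 0 from INT2, and windows of 5 Mb gave 2 from INT1.

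The replicate numbers do not pair the samples, since a DN and a B sample of the same number share no litter in the labels and their residuals correlated at r = -0.07, 0.09, 0.02 and 0.10. With replicate number as a block, all 8 anchors and 11 of 12 segments passed, windows numbered 27 from TEA, 56 from INT1, 26 from INT2 and 2 from Ed, and windows on other chromosomes 0 from INT1 and 1 from Ed. With the numbers crossed, the blocks gave 12, 58, 24 and 0 windows near the viewpoints.

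Leaving out each of the 4 samples in turn left 1 sample in a group, which is assumed to vary like the others. Anchors then ranged from 1.84 to 2.50 (TEA to INT), 1.14 to 1.68 (TEA to Ed), 1.44 to 2.59 (INT1 to TEA), 1.13 to 2.10 (INT1 to Ed), 2.29 to 3.05 (INT2 to TEA), 2.13 to 3.08 (INT2 to Ed), 1.84 to 2.60 (Ed to INT) and 0.88 to 1.51 (Ed to TEA). Upstream segments ranged from 1.67 to 2.29 (TEA), 2.48 to 2.90 (INT1), 1.98 to 2.47 (INT2) and 1.37 to 2.46 (Ed), inner segments from 1.83 to 2.31, 1.14 to 1.91, 2.44 to 2.65 and 1.15 to 2.33, and downstream segments from 1.23 to 1.57, 1.57 to 2.24, 1.68 to 2.05 and 0.29 to 0.48. Called windows ranged from 0 to 0 (TEA), 10 to 47 (INT1), 0 to 6 (INT2, all lower) and 0 to 16 (Ed), and windows on other chromosomes from 0 to 309, 0 to 155, 0 to 142 and 0 to 31.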

Other observations

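Chosen only after the result was seen were the description of the partner fragment and the tests of background, depth and sequencing folder, while the tests of the difference between INT1 and INT2 were written before their results were seen.

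In the INT region, the highest mean value from TEA lay on a fragment beside INT2. From TEA, this HindIII fragment at 54683880 to 54688070, next to the INT2 viewpoint fragment, ranked 1 in both DN samples and 2 in both B samples among the 586 fragments more than 10 kb away and within 1 Mb. The fragment was chosen as that maximum in the same TEA libraries, so the choice itself favours a high rank and ratio from TEA. It took 10.1% ± 1.80 of the reads within 1 Mb in DN thymocytes and 6.11% ± 0.362 in B cells (SD, n = 2). Compared with the mean of fragments within 20 kb of the same distance, it was 28.0 ± 1.89 times as high in DN and 22.4 ± 2.42 in B. INT2 in turn had the TEA fragment at ranks 1 and 3 in DN and 2 and 4 in B of 596 fragments, 11.5 ± 4.28 times its distance-matched mean in DN and 11.6 ± 0.893 in B. INT1 had the TEA fragment at ranks 13 and 3 in DN and 9 and 10 in B, 2.62 ± 0.316 times that mean in DN and 6.92 ± 1.65 in B. These differences were not tested.

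The share of chromosome 14 reads within 1 Mb was higher in DN than in B from all 4 viewpoints. Ligation background stays open. From TEA, INT1 and INT2 the difference was at least 8.46 points after the background expected from other chromosomes was subtracted, beyond the sum of the SDs. At INT1 it shrank from 29.8 points. The subtraction assumes that background on chromosome 14 equals the density on other chromosomes. That background made up 63.9%, 49.5% and 59.1% of B reads on chromosome 14 from TEA, INT1 and INT2. Beyond 1 Mb the B density was only 1.23, 1.23 and 1.27 times that on other chromosomes. A slightly higher background would therefore change the result, and the subtraction cannot decide. From Ed 5.73 points remained against a sum of SDs of 16.4, so background and cell type cannot be told apart there either. Lower depth of the DN libraries stays open: at INT1 the lower DN share exceeded the higher B share by 22.8 points, but DN replicate 1 alone was deeper than the B libraries there, and depth was not tested at the other viewpoints. The sequencing folder cannot be told apart from cell type, since 0 folders hold both, and genotype and tissue stay open as untested biological differences.

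Reads from INT1 fell more on the upstream side, relative to the inner side, than reads from INT2 in 4 of 4 samples, with upstream to inner ratios of 3.20 and 2.46 against 0.428 and 0.604 in DN, and 1.28 and 1.33 against 0.497 and 0.681 in B. The mean log2 difference was 1.82 (SD 0.85), with an exact sign-flip p of 0.125, the smallest that 4 samples allow. A few strongly amplified fragments are unlikely to be the whole cause, since the smallest difference was 0.38 with capped fragments (mean 0.99, SD 0.52, against 1.82 as deposited), while counting each captured fragment once, with a smallest difference of 0.060, decides nothing because both viewpoints captured 29 of 29 inner fragments in both DN samples. Subtracting the ligation background left at least 1.01 (mean 1.84, SD 0.83), which argues against background as the cause. Among fragments over 40 kb from both viewpoints the smallest difference was 0.90 where a 1/distance decay would give 0.19, and because that decay is an assumed profile the 5.09 kb offset stays open; no biological explanation was tested.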
